A study of Mus musculus with 8 samples.

How the data were processed

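Poly(A) RNA was sequenced from NIH3T3 cells, a mouse embryonic fibroblast line, after 1 day with Mic-628 or with vehicle. Each group had 4 libraries. Per the labels, total RNA was extracted with Trizol and libraries were made with a stranded mRNA kit and read as paired ends. The labels give each library a batch number from 1 to 4, and each number occurs in 1 vehicle and 1 Mic-628 library. They do not say whether the libraries of a group came from separate cultures, so p-values measure the spread between these libraries, which may be technical.

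Per the submitters' processing notes, bcl2fastq, STAR 2.7.10a and HOMER 4.11 were used with mouse build GRCm39 (mm39); the notes give no roles. The authors deposited a table of exon read counts, which are not whole but come in steps of 0.5 and are treated as estimated counts. It has 78298 rows, each a canonical transcript with its symbol, coordinates and exon length, and 39489 rows had a count in at least 1 library. The authors also deposited FPKM values for the same rows. Recomputing FPKM from the deposited counts, exon length and the library total in the file header gave values that differed by at most 5e-04. Coordinates are those of the deposited table, 1-based on mm39. The header totals ranged from 19.6 M to 25.1 M (M, mega) per library, and the counts on listed transcripts summed to 18.1 M to 23.2 M, between 92.2% and 93.2% of these totals. The column names were matched to samples by the library names in the labels, and 0 columns were left unmatched.

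The deposited counts were rounded to whole numbers and tested in R 4.3.3 with edgeR 4.0.16, using filterByExpr (minimum count 10), TMM normalization and the quasi-likelihood F test without a block, with Benjamini-Hochberg adjustment. Genes with an adjusted p under 0.05 are called changed, higher or lower. The filter left 17128 rows. TMM factors ranged from 0.9946 to 1.007, and the biological coefficient of variation was 3.47%. The standard error of a log2 fold change is its size divided by the square root of F. CPM values were scaled with TMM, and log2 CPM has a prior count of 0.5. Levels are given as mean ± SD over 4 libraries.

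Before the data were examined, the grouping, the main fit, 42 gene lists, the alternatives and the rule for named genes were fixed. The named genes are all tested members of the core clock list, and the 10 largest rises and 10 largest falls among called genes. The last 20 needed a mean CPM of at least 1, the same direction in all 4 same-batch pairs, and a symbol that is not a predicted or clone name. For each list described, the 2 to 4 members with the smallest p are named. Some genes that meet these rules are not reported here, though counts and list tests include them. Genes chosen after their values were seen are marked as such. Lists with at least 3 tested members were tested with camera (limma 3.58.1) at the preset inter-gene correlation of 0.01 and adjusted over the 39 lists that qualified. The same lists were tested with an estimated correlation and with fry. List means and ratios of genes were compared by exact permutation of the 8 library labels, two-sided, for which the smallest possible p is 0.0286 (0.02857 before rounding).

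Because the labels state a shared batch, the numbers pair the libraries, and a fit with the number as a block was an alternative. Deviations from the group means were not shared within pairs: over 10292 genes with a mean log2 CPM above 3, the correlations of same-numbered libraries were -0.0925, 0.0744, -0.0213 and -0.0949, within the range of the other pairs, -0.117 to 0.141. Other alternatives were DESeq2 1.42.0 with and without the block, DESeq2 size factors, upper-quartile scaling or library size only in edgeR, no low-count filter, a stricter filter (CPM of at least 1 in at least 4 libraries), limma-voom, limma-trend on log2(FPKM + 1) or log2(FPKM + 0.1) over rows with a mean FPKM of at least 0.5 or over all rows, a threshold of 0.01, and leaving out each library or batch in turn. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

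Pairs of replicates differed by more than counting noise: over 13066 genes, the chi-square per gene was between 1.73 and 5.79, so no library was treated as a duplicate. The test was run on simulated data drawn from the real means, library sizes and dispersions of this comparison, over 17128 genes. Of 50 genes changed at each fold size, it recovered 25 at 1.2-fold, 36 at 1.5-fold, 44 at 2-fold and 48 at 3-fold, with 6 false calls. In a second simulation over 16964 genes, camera called a list of 30 members moved by 1.2-fold and 0 of 100 random lists. The simulated genes varied independently of each other, unlike real genes.

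The kit keeps strand, but the counts may not use it. In 6 pairs where a row of 1 exon lies inside another on the opposite strand, 3 inner rows had over 0.5 of the outer row's FPKM. The other 3 had at most 0.0128 of it, so these pairs do not settle whether strand was used. Antisense or overlapping rows and near-identical genes, such as Hspa1a and Hspa1b, are therefore uncertain. The mitochondrial rows mt-Co2, mt-Atp6 and mt-Co3 had a mean log2 CPM of 3.70, 3.41 and 4.33, against 13.51 for mt-Co1; the reason was not tested, and the mitochondrial share given may be too low. The reference supplied was of an earlier mouse build; it was used only for the GC content of transcripts matched by identifier, and none of its coordinates are given.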

Results

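The data are 8 poly(A) RNA-seq libraries of NIH3T3 fibroblasts, 4 treated with vehicle and 4 with Mic-628 for 1 day. The series title describes a Period1 inducer that advances the circadian clock in mice. The comparison therefore asks which transcripts, and which clock transcripts above all, differed after 1 day of treatment. Between 18.1 M and 23.2 M counts per library fell on listed transcripts. The 10 most abundant transcripts took 7.18% to 7.57% of them, and mitochondrial transcripts took 2.82% to 3.36%.

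At an adjusted p under 0.05, a small part of the tested transcripts was called changed with Mic-628, mostly by modest amounts. Clock genes were among the most changed at both ends. Per1, a repressor in the core clock loop and an early target of clock-resetting signals, rose most, by 5.79-fold. The other largest rises were Gfra1, a co-receptor for the neurotrophic factor GDNF (2.96-fold); the inducible Hsp70 genes Hspa1a (2.88-fold) and Hspa1b (2.76-fold); Nr1d1, which encodes the nuclear receptor REV-ERB alpha (2.87-fold); Arl4d (2.43-fold); the natriuretic peptide gene Nppb (2.33-fold); the small heat shock protein gene Hspb7 (2.33-fold); Hes7 (2.32-fold); and the protease inhibitor gene Slpi (2.19-fold). Nppb and Hes7 were weakly expressed, at 0.62 and 0.64 CPM with vehicle and 1.45 and 1.49 CPM with Mic-628. The largest falls were in Per3, Nr1d2, Nlrp2, Gpr15lg, the glycoprotein hormone gene Stc1, Per2, Gdpd2, Tef, the chemokine gene Cxcl5 and the pro-apoptotic gene Bmf. Their log2 fold changes ran from -2.03 for Per3 to -0.80 for Cxcl5 and Bmf.

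By edgeR's quasi-likelihood test, 749 of 17128 tested rows changed, 364 higher and 385 lower. An unadjusted p under 0.05 was found for 2905 rows, and in simulation 25 of 50 genes changed by 1.2-fold were recovered. The count may therefore leave out small changes. The median absolute log2 fold change of the called rows was 0.21. Only 101 of them differed by at least 1.5-fold, 62 higher and 39 lower, and 28 by at least 2-fold, 26 higher and 2 lower. Those 2 were Per3 and the predicted gene Gm13549, the latter chosen after its values were seen (log2 fold change -1.13). With the batch number as a block the count was 624 in edgeR and 243 in DESeq2, against 558 in DESeq2 without it. It was 426 without vehicle replicate 2, 438 without Mic-628 replicate 3, 331 without batch 2 and 292 without batch 3, and the count of higher genes was 237 without vehicle replicate 3. Bmf was not called without vehicle replicate 2, Mic-628 replicate 1 or Mic-628 replicate 2 (edgeR adjusted p 0.0965, 0.0705 and 0.0524). Gpr15lg was not called without vehicle replicate 1 or 2 or Mic-628 replicate 1, 3 or 4 (0.0588, 0.126, 0.0808, 0.0990 and 0.0529). With the block in DESeq2, Nlrp2 and Bmf were not called (adjusted p 0.0826 and 0.428). By limma-trend on log2(FPKM + 1), Stc1, Gdpd2, Nlrp2, Gpr15lg, Bmf and Hes7 were not called (adjusted p 0.0627 to 0.124). Hes7 was not called without batch 4, Nppb without batch 2, and Cxcl5 without batch 2 or 3 (edgeR adjusted p 0.0878, 0.0506, 0.0633 and 0.0779). Hspa1a and Hspa1b are nearly identical and could exchange reads. Gfra1 and Hes7 each overlap an antisense row that also rose, Gm16277 (log2 fold change 1.63) and 9130213A22Rik (1.26), both chosen after their values were seen. Where the rows of a pair overlap, it is uncertain whether their reads can be told apart. Gm16277 went from a mean of 3.36 to 10.4 CPM, and Gfra1 from 22.4 to 66.4 CPM. Reads counted on both rows were therefore not the whole of the rise of Gfra1.

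Per1 (transcript ENSMUST00000021271.14, chromosome 11, 68989774 to 69000786, plus strand) had 21.5 ± 1.21 CPM (SD, n = 4) with vehicle and 124.5 ± 5.76 CPM (SD, n = 4) with Mic-628. Its log2 fold change was 2.53 (SE 0.046; edgeR adjusted p = 1.16e-22), which is 5.79-fold with a 95% interval of 5.42 to 6.17, and it was higher in 4 of 4 batch pairs. Nr1d1 (ENSMUST00000064941.7, chromosome 11, 98658758 to 98666159, minus strand) went from 48.1 ± 2.91 to 138.2 ± 4.32 CPM (SD, n = 4 each). Its log2 fold change was 1.52 (SE 0.040; edgeR adjusted p = 6.25e-19). Per3 (ENSMUST00000103204.11, chromosome 4, 151088109 to 151129122, minus strand) went the other way, from 11.8 ± 0.62 to 2.86 ± 0.333 CPM (SD, n = 4 each), a log2 fold change of -2.03 (SE 0.097; edgeR adjusted p = 1.22e-13).

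Of 24 core clock genes fixed beforehand, 20 were expressed highly enough to be tested, and 12 changed: 2 rose and 10 fell. Only Per1 and Nr1d1 rose. The other Period genes fell, Per2 with a log2 fold change of -0.86 and Per3 with -2.03, as did the cryptochromes Cry1 (-0.44) and Cry2 (-0.46). Bmal1, which encodes the activator that pairs with CLOCK, fell (-0.65), while Clock itself had a log2 fold change of 0.06 and was not called. Nr1d2, the paralog of Nr1d1, fell (-0.98). The PAR-domain transcription factor genes Dbp (-0.77) and Tef (-0.85) fell, as did Nfil3 (-0.55), whose product competes for their sites, and the activating receptor gene Rora (-0.33). The remaining 8 were not called, among them Clock, Hlf (0.60), Bhlhe40 (0.16), Bhlhe41 (0.00), Ciart (-0.25), Csnk1d (-0.07) and Csnk1e (-0.04). Adjusted over the list alone, 4 rose and 12 fell. Rora was close to the threshold (edgeR adjusted p = 0.0474) and was not called with the block (0.0803) or without any single library except vehicle replicate 4 (0.0529 to 0.153). Bhlhe40 was called without vehicle replicate 1 or Mic-628 replicate 3 (edgeR adjusted p 0.0253 and 0.0465). Per2 was not called without batch 3 (edgeR adjusted p = 0.0630) or with the block in DESeq2 (0.0807). Bhlhe41 changed sign between settings.

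**Figure D1:**
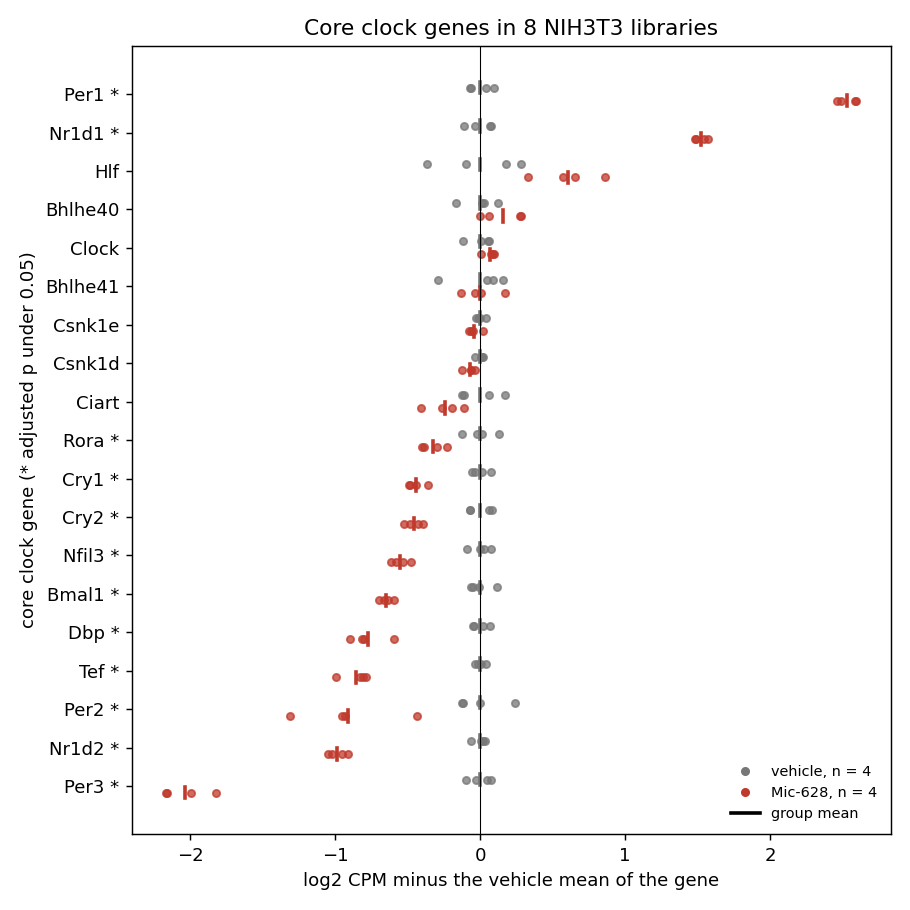
Core clock genes named in the text, one row per gene, with log2 CPM minus the gene's vehicle mean on the x axis; points are libraries (grey vehicle, red Mic-628), bars are group means and asterisks mark an adjusted p under 0.05. Per1 and Nr1d1 lie to the right at 2.53 and 1.52, and 10 genes from Rora to Per3 lie to the left.

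The title calls the action specific, so Per1 was compared with the other genes driven through E-boxes, the DNA elements bound by CLOCK and BMAL1. Per1 rose relative to their mean by 2.83 on the log2 scale, or 7.13-fold. The log2 ratio was 0.43 ± 0.12 with vehicle and 3.26 ± 0.021 with Mic-628 (SD, n = 4 each). The exact permutation p was 0.0286, the smallest that 4 libraries against 4 can give. Per1 also rose relative to each of the 14 other members tested singly, with the same exact permutation p (0.0286 after Benjamini-Hochberg adjustment over the 14). The smallest of these differences was against Nr1d1, 1.01 on the log2 scale, and the largest against Per3, 4.57. Within batches the difference was again 2.83, with an exact sign-flip p of 0.125, the smallest that 4 pairs allow. Of the 15 E-box genes, 2 rose and 7 fell, and adjusted over the list alone 4 rose and 8 fell. Their median log2 fold change was -0.25 and their mean -0.11, while camera placed the list upward without calling it (adjusted p = 0.87), so the signs differ. The 2 that rose were Per1 and Nr1d1.

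Both risers had neighbours that rose as well, chosen after their values were seen. On the Per1 side of chromosome 11, Vamp2 (68979316 to 68983210; log2 fold change 0.41) and Tmem107 (68961632 to 68963856; 0.45) lie upstream of Per1, and Hes7 (69011230 to 69014881; 1.22) lies downstream, all on the plus strand. Borcs6 (0.02), Aurkb (0.11) and Aloxe3 (0.67) in the same stretch were not called. Beside Nr1d1, the thyroid hormone receptor gene Thra (98632699 to 98655937, plus strand; 0.62) and the predicted gene Gm57390 (0.68) rose. Med24 (0.03) and Msl1 (0.11) were not called. The edgeR adjusted p was 2.97e-06 for Vamp2, 0.00536 for Tmem107 and 8.05e-11 for Thra.

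**Figure D2:**
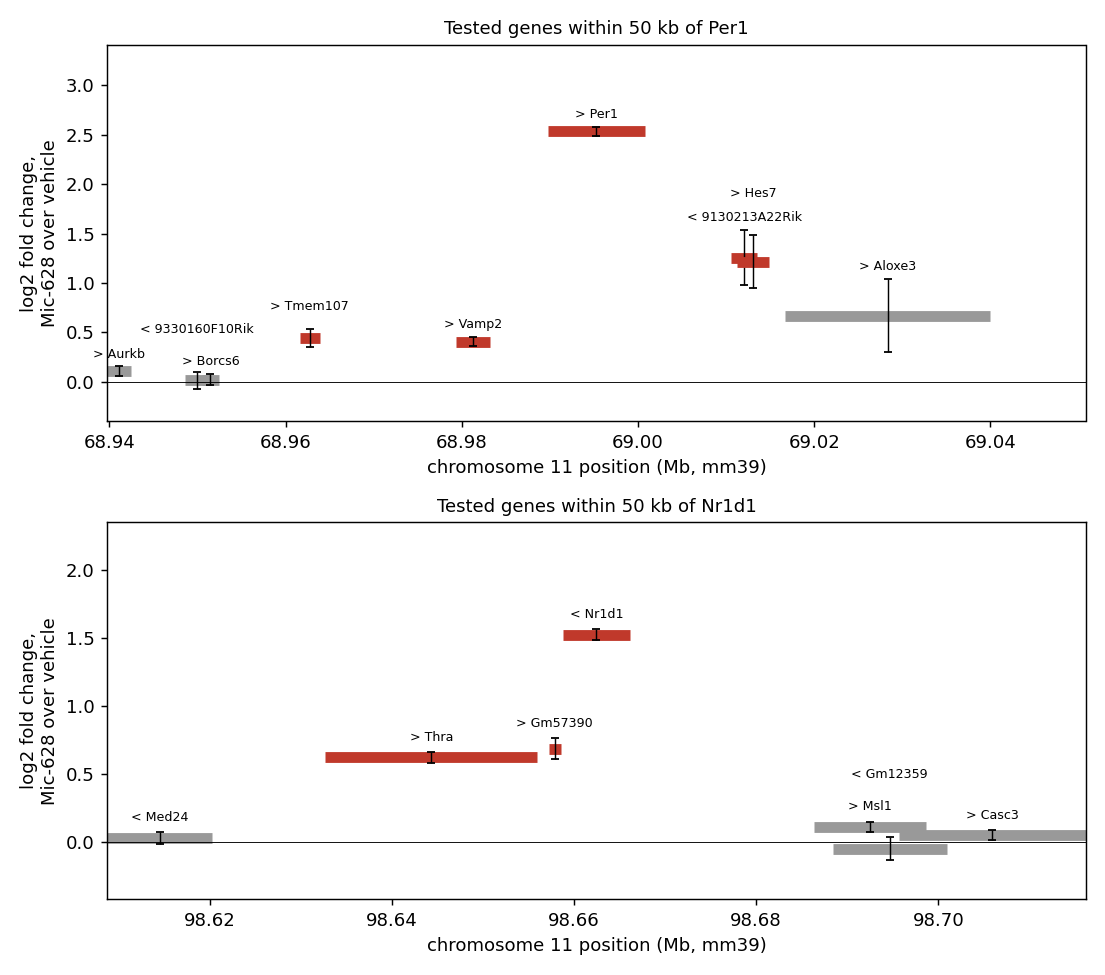
Tested genes within 50 kb of Per1 (top) and Nr1d1 (bottom), with chromosome 11 position in Mb (mm39) on the x axis and log2 fold change of Mic-628 over vehicle on the y axis; thick bars span the genes, red if called higher and grey if not called, error bars are SE, and > and < give the strand. Per1 stands at 2.53 with Vamp2 and Tmem107 at 0.41 and 0.45, and Nr1d1 at 1.52 with Thra at 0.62.

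Of 39 tested gene lists, the core clock among them, 13 were called by camera with the preset correlation, 7 upward and 6 downward. With an estimated correlation 3 of the 13 were called: extracellular matrix, genes controlled through ROR/REV-ERB elements, and the TGF-beta and BMP response. Other divisions of the same 8 libraries gave up to 16 called lists with the preset correlation where 3 libraries of each group stayed together, up to 9 where 2 did, and 0 with an estimated correlation. Fry, which asks whether the genes of a list move one way, called 12 of the 13. For these 12 the exact permutation p of the list mean was 0.0286, the smallest possible. After Benjamini-Hochberg adjustment over the 39 lists it was 0.0655. For the other, hypoxia and glycolysis, the adjusted exact permutation p was 0.152. None of the 13 was called by the adjusted permutation test. With 17 of the 39 lists at the smallest possible p, 0.0655 was the lowest adjusted value. That test could therefore call no list, however large its difference. The core clock list was called downward (camera adjusted p = 0.00432; adjusted p = 0.283 with an estimated correlation), but not without Mic-628 replicate 3 (camera adjusted p = 0.108).

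Genes of the extracellular matrix, the secreted scaffold that fibroblasts make, fell together. Of 20 tested members, 13 fell, 0 rose and 7 were not called, and 16 fell when adjusted over the list alone. Col3a1 fell from 88.6 ± 10.4 to 59.6 ± 4.58 CPM (SD, n = 4 each; log2 fold change -0.57), Col12a1 by a log2 fold change of -0.60, and the abundant Fn1, which encodes fibronectin, from 14210 ± 847 to 11730 ± 203 CPM (SD, n = 4 each; -0.28). The proteoglycan gene Bgn fell too (-0.19). Col1a1, a type I collagen gene chosen after its values were seen, was not called (-0.0044). The camera adjusted p was 1.90e-17, and the adjusted p was 0.0251 with an estimated correlation.

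Of the 4 tested genes controlled through ROR and REV-ERB elements, 3 fell (Bmal1, Nfil3 and Cry1) and Clock was not called; adjusted over the list alone, the count was also 3. The camera adjusted p was 1.98e-11, and the adjusted p was 0.0138 with an estimated correlation. Inflammatory genes downstream of NF-kB had 5 of 14 members lower, 6 when adjusted over the list alone, and 0 higher. Among them were the chemokine genes Ccl2 (log2 fold change -0.62) and Cxcl5 (-0.80) and the cytokine gene Csf1 (-0.19). The camera adjusted p was 0.000605, and the adjusted p was 0.0656 with an estimated correlation. Cxcl5 was not called without batch 2 or 3 (edgeR adjusted p 0.0633 and 0.0779). Among hypoxia and glycolysis genes 10 of 22 fell and 1 rose, or 14 and 1 when adjusted over the list alone. The glycolytic enzyme gene Pfkl (-0.30) and the kinase gene Pdk1 (-0.37) fell, and Hk2, the hexokinase gene, rose (0.31). The list means of both groups overlapped (exact permutation p = 0.0857), and the camera adjusted p of 1.34e-08 became an adjusted p of 0.362 with an estimated correlation and 0.150 with fry. Of 10 tubulin genes 3 fell, also 3 when adjusted over the list alone, with Tubb2b (-0.31) and Tubb5 (-0.15) the clearest. That list had a camera adjusted p of 0.0117, an adjusted p of 0.298 with an estimated correlation, and 0.0764 without Mic-628 replicate 2. Tubb5 was not called without batch 2 (edgeR adjusted p = 0.0635).

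**Figure D3:**
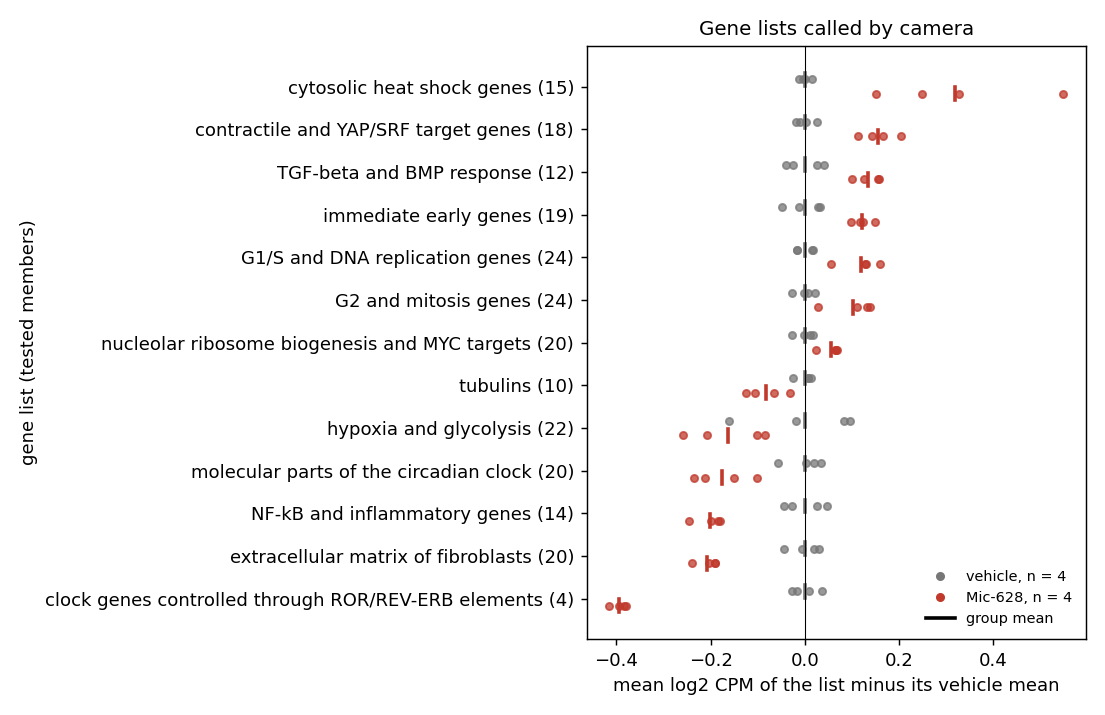
The 13 called gene lists, one row each with the number of tested members, and the mean log2 CPM of the list minus its vehicle mean on the x axis; points are libraries (grey vehicle, red Mic-628) and bars are group means. Hypoxia and glycolysis is the list whose groups overlap, and the heat shock points of Mic-628 are the most spread.

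Of 15 cytosolic heat shock genes 5 rose, 10 when adjusted over the list alone, 0 fell and 10 were not called. The list had a camera adjusted p of 1.34e-08 and an adjusted p of 0.133 with an estimated correlation. The rise was uneven across libraries. Hspa1b had 11.5 ± 0.616 CPM with vehicle, and 21.4, 19.3, 31.6 and 54.2 CPM in Mic-628 replicates 1 to 4. Cryab, a small heat shock protein gene, rose more evenly (log2 fold change 0.43). Hspa1a and Hspa1b were not called by limma-trend on log2(FPKM + 1), with adjusted p of 0.114 and 0.0639.

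Of 24 G2 and mitosis genes 6 rose and 0 fell, and 13 rose when adjusted over the list alone. The camera adjusted p was 1.34e-08, and the adjusted p was 0.238 with an estimated correlation. The spindle gene Prc1 (log2 fold change 0.17) and the proliferation marker Mki67 (0.16) had the smallest p. Of 24 S phase genes 7 rose and 0 fell, or 12 and 0 adjusted over the list alone, led by the helicase subunit gene Mcm6 (0.15) and Uhrf1 (0.13). For this list the camera adjusted p was 4.43e-08, and the adjusted p was 0.180 with an estimated correlation. Mki67 was not called without vehicle replicate 2, Mic-628 replicate 1 or Mic-628 replicate 3 (edgeR adjusted p 0.0564, 0.0791 and 0.0637). Mcm6 was not called without vehicle replicate 2 or Mic-628 replicate 1 (edgeR adjusted p 0.118 and 0.0600), nor Uhrf1 without vehicle replicate 2, Mic-628 replicate 3 or Mic-628 replicate 4 (0.113, 0.0805 and 0.0503). Prc1 was not called without batch 3 (0.0785). With the block in DESeq2, Prc1, Mki67, Mcm6 and Uhrf1 were not called (adjusted p 0.0699, 0.134, 0.290 and 0.274). Ribosome biogenesis and MYC target genes had 3 of 20 members higher, 4 adjusted over the list alone, including Odc1 (0.15) and Nop58 (0.13). That list had a camera adjusted p of 0.00137 and an adjusted p of 0.298 with an estimated correlation. Odc1 was not called without Mic-628 replicate 3 (edgeR adjusted p = 0.0532), and Nop58 not without vehicle replicates 2 or 3 or Mic-628 replicates 1 or 3 (0.112, 0.0728, 0.0700 and 0.118). With the block in DESeq2 neither was called (adjusted p 0.0510 and 0.150).

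Among contractile and YAP/SRF target genes 6 of 18 rose and 2 fell, or 7 and 2 adjusted over the list alone. Ccn1 rose (log2 fold change 0.23), and so did the smooth muscle actin gene Acta2 (0.20), while the YAP target gene Amotl2 fell (-0.16). The camera adjusted p was 1.34e-08, and the adjusted p was 0.133 with an estimated correlation. Of 12 TGF-beta and BMP response genes 2 rose, among them Id2 (0.44), and 3 adjusted over the list alone. The other 10 were not called and the median of the list was 0.02, so its call rested on few members (camera adjusted p = 4.72e-07; adjusted p = 0.0266 with an estimated correlation). Immediate early genes had 4 of 19 members higher and 1 lower, or 6 and 1 adjusted over the list alone. Atf3 (0.45) and the phosphatase gene Dusp1 (0.41) rose, as did Klf4 (0.23), and Junb fell (-0.24). The camera adjusted p was 0.00324, and the adjusted p was 0.0884 with an estimated correlation. Amotl2 was not called without batch 2 or 3 (edgeR adjusted p 0.0673 and 0.0988), and Junb not with the block in DESeq2 (adjusted p = 0.0592).

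The remaining 26 lists were not called by camera. Fry called 3 of them, aryl hydrocarbon receptor targets (adjusted p = 0.0202), macrophage and blood cell markers (0.0258) and genes of xenobiotic handling (0.0258). Glucocorticoid receptor targets went both ways, with 4 of 12 rising and 3 falling (4 and 6 adjusted over the list alone). Klf9, an early steroid target gene, rose most clearly (log2 fold change 0.55), and Dusp1 (0.41) and Tsc22d3 (0.25) rose too. The median was -0.05 and the mean 0.04, so their signs differ, and camera placed the list upward (adjusted p = 0.0712). Of 6 aryl hydrocarbon receptor targets 3 rose and 1 fell (4 and 1 adjusted over the list alone), with Nqo1 (0.23) and the weakly expressed Aldh3a1 (1.21) higher and Cyp1b1 (-0.17) lower (camera adjusted p = 0.0525). This list was called without vehicle replicate 2 or 3 or Mic-628 replicate 2 or 3 (camera adjusted p 0.0416, 0.0421, 0.0218 and 0.0483), and the glucocorticoid list without vehicle replicate 1 or 2 or Mic-628 replicate 2 or 3 (0.0301, 0.0416, 0.0223 and 0.0419). With no low-count filter both lists were called (camera adjusted p 0.0172 and 0.0294), and with library size only the aryl hydrocarbon receptor list was called (0.0462). Nqo1 was not called without vehicle replicate 3 or Mic-628 replicate 3 (edgeR adjusted p 0.0532 and 0.0646), nor Cyp1b1 without vehicle replicate 2, vehicle replicate 3 or Mic-628 replicate 4 (0.0595, 0.0523 and 0.0617), nor Aldh3a1 without vehicle replicate 1 or 2 or Mic-628 replicate 1 or 4 (0.0594, 0.0746, 0.0808 and 0.0539). With the block in DESeq2, Nqo1 and Cyp1b1 were not called (adjusted p 0.311 and 0.176). Of 15 unfolded protein response genes of the endoplasmic reticulum, 0 were called by edgeR or adjusted over the list alone (camera adjusted p = 0.0510). Markers of adipocytes, skeletal muscle, bone and cartilage, and macrophages or blood cells had 3 tested members each (camera adjusted p 0.855, 0.750, 0.128 and 0.172). Epithelial, endothelial and neuronal markers had 2 tested members each and were not tested as lists.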

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

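Of 174 groups of 4 libraries tested, covering the named genes and the measures of each library, 2 had a library far from the other 3, where chance alone gives about 8.7. Tubb2a had 26.3 CPM in Mic-628 replicate 1 and 29.0 to 29.5 CPM in the other Mic-628 libraries. Atf3 had 59.6 CPM in Mic-628 replicate 4 and 51.6 to 52.6 CPM in the other Mic-628 libraries. No explanation was tested for either.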

How the results depend on the processing

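All settings here were planned except the heat shock list without Hspa1a and Hspa1b, chosen after seeing the data. No called gene shared with another setting changed sign in any setting. Counts of changed, higher and lower genes beyond 1.5 times the reported ones were 243, 130 and 113 with the replicate block in DESeq2; 277, 156 and 121 on log2(FPKM + 1); 273, 153 and 120 on log2(FPKM + 0.1); 170, 107 and 63 on log2(FPKM + 1) with no filter; and 330, 173 and 157 at a threshold of 0.01, which is stricter by construction. For the others the cause was not tested. Leaving out 1 library or batch gave 292 to 802 changed genes, 164 to 412 higher and 128 to 429 lower. Per1 had a log2 fold change of 2.49 to 2.57 there and 2.29 to 2.54 in the other settings, always called. The count of core clock genes was 10 to 12 in all settings. The replicate block in edgeR gave 624 changed genes and ended the calls of Rora, Mcm4, Tuba1a, Nop56 and Ugt1a6a among named genes; in edgeR and camera it changed no other named call. With the block in DESeq2, Rrm2, Tpx2, Per2 and other genes given above with their values were not called; P4ha2, Ccl7 and Bub1 were not called in DESeq2 with or without it.

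The list count fell from 13 to 3 with an estimated correlation, and the cause was not tested. For NF-kB and immediate early genes the estimated correlation was -0.0049 and -0.0051, below the preset 0.01. More correlation between members was therefore not why these lists lost their calls. Without 1 library the list count at the preset correlation was 13 to 16. Heat shock without Hspa1a and Hspa1b was still called (adjusted p = 1.43e-05). Per1 against the other E-box genes was 2.80 to 2.89 without 1 library, where the exact permutation p of 0.0571 is the smallest that 3 against 4 allow, and 2.83 with sign flips within batches as a replicate block (p = 0.125), fewer arrangements being the cause. Bhlhe41 reversed to -0.003488 with upper-quartile scaling, -0.002715 on log2(FPKM + 1) with or without the filter and -0.002202 on log2(FPKM + 0.1), and ran from -0.0869 to 0.0653 in leave-outs; it was never called. The E-box list turned downward without vehicle replicate 2 (adjusted p = 0.998) or 4 (0.836), with a range of 0.279 to 0.998 and no call. Of 69 called named genes, Per1 and 19 others kept the call in every setting that tested them, and 50 kept it without each single library. In simulation at the depth, number of libraries and spread of these data, 25 of 50 genes changed by 1.2-fold were recovered; these were not varied.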

Other observations

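The genes in this part were chosen after their values were seen, as were all tests here except the splits counting genes, core clock genes and lists at the preset correlation, the first neighbour test, and the single-library and length or GC tests. Nuclear receptor genes beyond the clock moved in both directions. Rarg, a retinoic acid receptor gene, rose (log2 fold change 0.37), while its relative Rara (-0.19), the vitamin D receptor gene Vdr (-0.46) and the orphan receptor gene Nr2f1 (-0.35) fell. Of 26 tested nuclear receptor genes, 8 were called. Leaving out the core clock members, 5 of 23 were called. Among genes of glycolytic and related enzymes, some also on the fixed list, 13 of 19 fell, among them Pgam1 (-0.17) and Gpi1 (-0.14), and 2 rose. The fixed hypoxia and glycolysis list, which overlaps them, was not called with an estimated correlation (adjusted p = 0.362) or with fry (adjusted p = 0.150).

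Single genes of other kinds changed as well. The integrin gene Itgb7 rose from 58.0 ± 2.12 to 107.3 ± 4.35 CPM (SD, n = 4 each; log2 fold change 0.89). The tissue factor gene F3, which starts coagulation, rose by 0.69 on the log2 scale, and Thbd, which encodes the anticoagulant thrombomodulin, by 0.26. Has2, a hyaluronan synthase gene, fell (-0.47), and the ceruloplasmin gene Cp fell (-0.56). Of 8 tested frizzled genes, which encode Wnt receptors, 3 fell, Fzd1 (-0.25), Fzd2 (-0.25) and Fzd8 (-0.28), and the median of the 8 was 0.02. The fixed list of Wnt targets was not called (camera adjusted p = 0.973). The nuclear RNA Malat1 rose (0.61), from 554.7 ± 98.1 to 846.5 ± 69.3 CPM (SD, n = 4 each).

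Of the 35 splits of the 8 libraries into 4 and 4, only 1, the real one, gave as many as 749 changed genes. The highest other gave 1, and the 7 others that part all 4 batch pairs gave 0. A share of 1 in 35 is the smallest these splits can give, and 1 in 8 among those that part all pairs. Splits that mix the groups also add any treatment difference to the spread within groups, which lowers their counts. The splits alone therefore do not exclude chance. For the 12 core clock genes, 1 split was as high, the real one, and the highest other gave 0, with the same limits. The count of lists at the preset correlation did not set the real split apart: 7 of the 35 splits called 13 or more, the highest other 16, also among splits that part all pairs. The 6 others among these keep 3 libraries of each group together, and so part of any treatment difference, while the 18 splits that mix 2 with 2 called at most 9. With an estimated correlation, a test added after that result, 1 split called 3 lists and the highest other 0.

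The first pattern is the rise of genes beside Per1 and Nr1d1. Vamp2 and Tmem107 end upstream of Per1 on its strand, so transcription past the end of Per1 does not reach them, and the smaller of their log2 fold changes was 0.4062; the shortest gap to Per1, 6563 bases, argues against reads counted on overlapping rows. The canonical transcript row of Thra lies 2820 bases from that of Nr1d1. It gained 8.7 more FPKM than Gm57390, the row between them (exact permutation p = 0.0286). That argues against transcription past the end of Nr1d1 as the whole of the rise of Thra. A part of it stays open, since Gm57390 gained 3.22 FPKM and Thra 11.9. Gm57390 lies 184 bases past the end of Nr1d1. For Gm57390 and for Hes7, downstream of Per1, such transcription was not tested. Whether genes near any riser rise was tested on 133 neighbours within 50 kb of 44 other risers. Their mean log2 fold change of 0.035 lay at percentile 99 of 10000 draws, but their median was 0.0065 and 52.6% were above 0. The typical neighbour thus differed far less than the called genes beside Per1 and Nr1d1. Those were picked because they rose, and other neighbours at both loci were not called. The test was then repeated, after the first percentile was seen, without 3 rows that overlap a riser, and the percentile was 88.7. The answer therefore rests on 3 rows whose reads may not be assignable, and it stays open. A shared regulatory region at either locus may contribute and was not tested.

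The second pattern is that Nr1d1 rose while its paralog Nr1d2 fell, as did Dbp, Tef and Per3, which usually peak near it. Reads passed from Nr1d2 to Nr1d1 would leave the sum of both as it was, but it went from 122.1 ± 2.21 to 175.6 ± 5.77 CPM (SD, n = 4 each). This difference of 53.5 CPM (exact permutation p = 0.0286) argues against such reads as the whole of the rise of Nr1d1. If the share of reads passed was the same in both groups, it could not add to either change, since passed reads follow the gene they come from. Whether the share differed between the groups was not tested and stays open. A shift of phase and repression of Bmal1, Nfil3 and Cry1 by the product of Nr1d1 were not tested, since there is 1 time point and protein was not measured.

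The third pattern is the fall of matrix genes beside the rise of cell cycle and heat shock genes. No single library carried it: the smallest share of a list's difference kept was 0.762, for heat shock without Mic-628 replicate 4. After trends with transcript length, GC content and expression were removed, the largest of the 4 list p-values was 4.51e-07, which argues against these biases as the whole cause. That p takes the preset correlation, and of these 4 lists only matrix holds with an estimated one. A difference in cell density between the groups and an effect of Mic-628 on growth were not tested and remain open.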
